A study of Drosophila melanogaster with 16 samples.

How the data were processed

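The values are the deposited log2 expression values of Affymetrix Drosophila 2.0 oligonucleotide arrays, computed by the authors with GCRMA per the submitters' processing notes, which give no version. GCRMA corrects for background binding with probe sequence and quantile normalizes the arrays against each other, so a change in the total RNA of a head cannot be seen in them. Per the labels, RNA was extracted from heads with Trizol, labelled with biotin and hybridized. Per the series design text, adult males of the Berlin background aged 2 to 4 days breathed a 60% dilution of saturated ethanol vapor, or humidified air alone, for 30 min and were frozen after 0, 30, 60 and 90 or 120, 180 and 210 min of recovery. Each exposed array is 1 pool of 3 groups of 200 flies, joined before extraction, and 2 arrays of unexposed flies (A and B) complete the 16. Each exposure and time has 1 array, so the spread between pools of the same time was not measured. For ethanol against air, the p-values measure the spread of the 7 matched ethanol minus air differences.

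The array carries 18952 probe sets; 183 controls were left out, and 18769 were used. Probe sets were given gene symbols by Entrez ID from the array annotation and the RefSeq gene table: 13647 had 1 symbol, 402 had several and 4720 had none. Probe sets with several or no symbols were tested and counted but never named, and they entered no gene list. Where a gene had several probe sets, the one with the highest mean was used, which applied to 782 kept genes. A gene was kept when it reached log2 4 in at least 3 of the 16 arrays, leaving 8110 of 17104 (7104 named, 1006 without a single symbol). Positions are on the Release 6 assembly.

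Differences were tested with limma 3.58.1 (linear models with empirical Bayes variances) and Benjamini-Hochberg adjusted p-values, called at adjusted p < 0.05. Ethanol against air was fitted with the time point as a factor, so each ethanol array is compared with the air array of its own time. The change of that difference with time was fitted as a slope per hour, and 3 windows (early 0 and 30 min, middle 60 and 90 min, late 120, 180 and 210 min) were fitted in 1 model. The windows shared 1 spread, with 4 residual degrees of freedom. Air against unexposed was taken from a model with 3 groups over all 16 arrays, and the time course in air from a slope over the 7 air arrays. In the model with 3 groups the spread is that within the groups and includes the change over time after exposure. For the slope in air it is that of the air arrays around their line. The software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

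Gene lists were written from general knowledge of fly biology. Of 35 lists, 33 had at least 3 kept genes and were tested with camera, which compares a list with all other genes and here assumes a correlation of 0.01 between its members, adjusted over the lists. Each was also tested with a correlation estimated from the residuals and with fry. For ethanol against air, each also had an exact sign-flip test over 64 sign sets, whose smallest possible p is 0.0156. The Turandot and chemoreceptor lists kept 1 gene each and were not tested as lists. 3 list entries written by mistake (2 in the clock list, 1 in the fat body list) were left out before any value was seen. Genes counted as "adjusted over the list alone" had their p-values adjusted among the list's members only.

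The rule for named genes took the 10 largest rises and falls past the threshold (for ethanol against air, with the same sign at 6 or more of 7 times), 5 of each in the windows, and the 5 smallest p-values in each direction as values where none passed. Up to 4 members of each list that passed were named, and a set of ethanol, clock, stress and activity genes always. Comparisons, tests, filter, lists, this rule and the first alternatives were chosen before the data were examined.

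The alternatives were no filter and a filter at log2 6, quantile or median scaling, all probe sets of a gene, limma with trend and robust variances, array weights, adjusted p < 0.10, a 1.5-fold minimum, no matching by time (minutes as a linear term or left out), and leaving out 1 time pair or 1 array. After body-tissue transcripts were found in 4 arrays, 2 more were added: leaving out those arrays or time pairs, and a body-tissue score as a covariate. The slope of the mean of the air and ethanol array of each time was also added after results were seen. The models were tested on simulated data with 8110 genes, of which 200 changed; of 2-fold changes, 100% were recovered for ethanol against air, 47.8% for a slope with time, 80.6%, 89.6% and 91% for the early, middle and late windows, 91% for air against unexposed and 82.1% for the slope in air, none with the wrong sign. The simulated noise was normal and drawn independently for each gene and array. Noise shared by many genes, as from body-tissue transcripts, was not simulated, so the recovered shares may be lower in the real arrays. A count of 0 calls therefore does not exclude 2-fold changes. The pairing by time was checked on the correlation of the ethanol and air arrays around the mean of their exposure: 5 of 7 ethanol arrays matched the air array of their own time best. The closest match was at 120 min (0.759), where both arrays carry body-tissue transcripts. Those at 0 and 60 min (-0.093 and -0.079), where only the air array does, did not match. At these times the check cannot separate shared time from body tissue. Adh, Aldh, homer, Hsp22, Hsp70Aa, Thor and to had no kept probe set of a single gene and are not analysed here. Behavior, hemolymph ethanol and single flies were not analysed here.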

Results

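Heads of adult male Drosophila melanogaster were profiled on arrays after 30 min of ethanol vapor (7 arrays) or humidified air (7 arrays), with 1 array for each exposure at 0, 30, 60 and 90 and at 120, 180 and 210 min of recovery, and in unexposed flies (2 arrays). Each array is a pool of heads from 3 groups of 200 flies, or for the unexposed arrays from untreated flies. Array medians lay between 2.88 and 3.03 log2, and 44.7% to 45.5% of probe sets reached log2 4, an evenness that the normalization of the deposited values sets by itself. The 2 unexposed arrays differed by at least 1 log2 unit in 5 genes (4 higher in A, 1 lower), whereas the ethanol and air arrays of 1 time differed by that much in 75 (30 min) to 134 (180 min) of 8110 genes at 30, 90, 180 and 210 min. They did so in 207, 206 and 172 genes at 0, 60 and 120 min, whose air arrays carry male reproductive tract and gut transcripts.

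Among genes with a single symbol, the 10 largest falls after ethanol include antennal and odorant-binding protein genes. The antennal protein gene a5 (probe set 1628647_at; chromosome 2L, 1329161 to 1329993) averaged 8.42 log2 after air (SD 0.62, n = 7), 5.97 after ethanol (SD 0.37, n = 7) and 8.36 in unexposed heads, a fall of 2.44 (SE 0.23, adjusted p = 0.00458). The odorant-binding protein genes Obp59a (probe set 1627935_a_at; chromosome 2R, 22702695 to 22703786) and Obp84a (chromosome 3R, 7250725 to 7251957) fell by 2.40 (SE 0.34, adjusted p = 0.0201) and 2.39 (SE 0.32, adjusted p = 0.0181), from 6.55 and 5.99 after air. Jhedup, a juvenile hormone esterase duplication, fell by 2.17 (SE 0.21) and the glutathione S-transferase gene GstE4 by 2.14 (SE 0.19), both with adjusted p = 0.00458. Also lower were Os-C (-2.09, adjusted p = 0.0119), Obp19a (-1.82, 0.015), Obp69a (-1.80, 0.0201), Obp83b (-1.77, 0.0231) and lush, whose product binds alcohols and a male pheromone (-1.76, 0.0333). Each of these 10 genes was lower after ethanol at 7 of 7 times. Among genes chosen after their values were seen, a10 fell by 1.68 (adjusted p = 0.00458) and Orco, the co-receptor of most odorant receptors, by 1.46 (adjusted p = 0.0392). In unexposed heads the same genes stood near their level after air (Obp59a 6.54, Obp84a 6.17, Jhedup 9.28, GstE4 8.19, Os-C 10.47).

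Among genes with a single symbol, CG32512 had the largest called rise. It (probe set 1637936_at; X chromosome, 21062277 to 21067540) rose by 1.55 log2 (SE 0.22, adjusted p = 0.0201), from 6.60 after air (SD 0.19, n = 7) to 8.15 after ethanol (SD 0.71, n = 7), with 6.26 in unexposed heads. Larger called rises were those of 3 probe sets shared by several genes (3.62, 2.59 and 2.20). CG9733 rose by 1.20 (SE 0.14, adjusted p = 0.0119), the glutathione S-transferase gene GstE7 by 1.16 (SE 0.16, adjusted p = 0.0201) and Nmdmc, a folate-pathway enzyme of mitochondria, by 1.16 (SE 0.16, adjusted p = 0.0209). GstD2 rose by 1.11 and the serpin gene Spn27A by 1.05 (both adjusted p = 0.0119), the peroxiredoxin gene Prx6c by 1.02 (0.027), Agpat2 by 1.0 (0.015), CG6675 by 1.0 (0.0144) and CG33110 by 0.96 (0.00458). Men, the malic enzyme gene, rose by 0.84 (adjusted p = 0.0272), Arc2 by 0.66 (0.0119), the cytochrome P450 gene Cyp6d5 by 0.46 (0.0474) and the potassium channel gene Irk1 by 0.36 (0.0327). All 14 were higher after ethanol at 7 of 7 times. CG9733, GstE7 and Nmdmc stood at 7.21, 9.57 and 9.61 after air and at 5.95, 9.24 and 9.13 in unexposed heads.

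**Figure D1:**
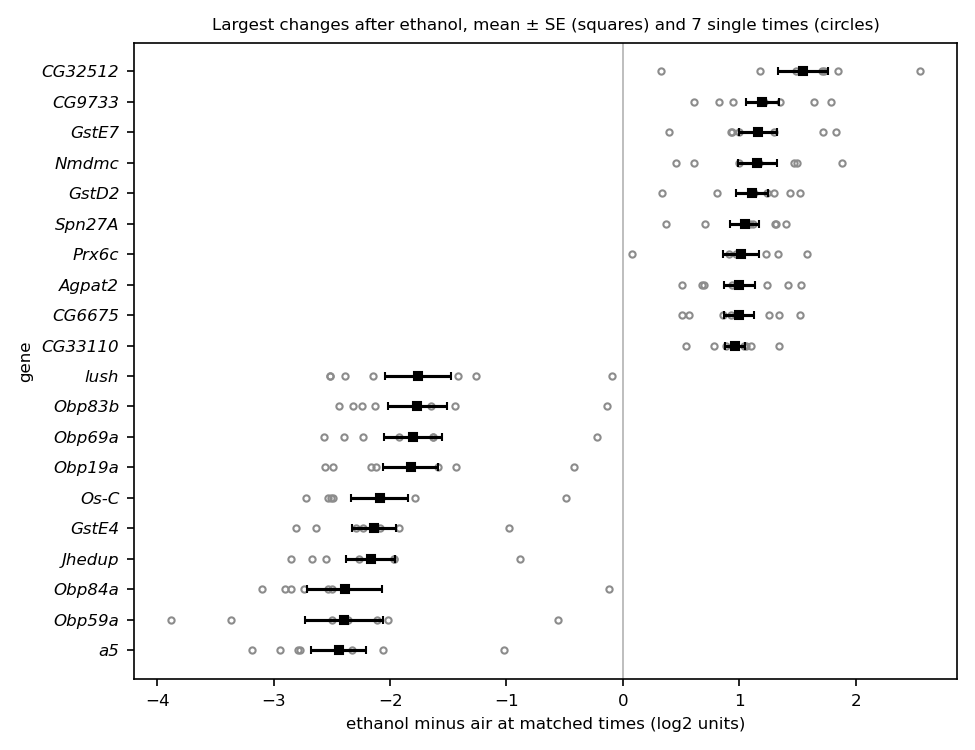
Ethanol minus air difference (log2, x axis) of the 10 largest rises and 10 largest falls among called genes with a single symbol; squares are means with SE over 7 times and circles are single times. The circles of each gene lie on 1 side of zero.

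In all, 34 genes were higher and 22 lower after ethanol at adjusted p < 0.05, with 980 at unadjusted p < 0.05; the median absolute change of the called genes was 1.0 log2. The balance turned to 45 higher and 59 lower without the 0 min pair, to 8 and 16 without the 0, 60 and 120 min pairs, and to 18 and 28 with a body-tissue covariate. The count of 56 moved to 104 without the 0 min pair, 22 without 30 min, 8 without 60 min, 24 without 90 min, 9 without 120 min and 16 without 210 min. It was 0 without an expression filter and 24 without the 0, 60 and 120 min pairs, whose air arrays carry body-tissue transcripts. Of 25 named calls, 5 were kept without 60 min, 5 without 120 min, 9 without 210 min, 12 without 30 min, 14 without 90 min, 19 without 180 min and 25 without 0 min.

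Several genes named in advance for ethanol, clock and stress did not pass over all times. AcCoAS, which makes acetyl-CoA from acetate, had a difference of 0.68 log2 (SE 0.13, adjusted p = 0.0701, above air at 7 of 7 times). Hsp26 had 0.75 (SE 0.15, adjusted p = 0.0804, 7 of 7 times), Hr38 0.57 (adjusted p = 0.38), hang 0.17 (0.47), slo 0.11 (0.577), sr 0.23 (0.513) and kay 0.00 (0.994). The clock genes per (0.23, adjusted p = 0.303), tim (0.19, 0.306) and vri (0.20, 0.631) did not pass, nor did sug (0.17, 0.946) or the antifungal peptide gene Drs (0.13, 0.859). Adh, Aldh, homer, Hsp22, Hsp70Aa, Thor and to are not analysed here.

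Of 33 gene lists, 6 stood higher after ethanol as a whole. The heat shock list (11 genes, median 0.33) had 9 positive members, 0 called among all genes and 5 rising adjusted over the list alone. These 11 are what was kept of 27 genes written for the list, without Hsp22 and Hsp70Aa. Probe sets shared by several genes entered no list, so the 0 says nothing of heat shock genes outside the 11. Its members include Hsp68 at 0.89 (adjusted p = 0.157) and Hsp27 at 0.65 (0.173). The list as a whole passed camera (adjusted p = 8.64e-05, and 0.0815 with an estimated correlation). Its median was above 0 at 7 of 7 times (exact sign-flip p = 0.0156 unadjusted, 0.172 adjusted over the lists). No list passed the sign-flip test after adjustment. Unadjusted, only the heat shock, ion channel, hemocyte and odorant-binding protein lists had sign-flip p under 0.05. The activity-regulated list (16 genes, median 0.21) had 2 rising, Arc2 and Irk1, 14 not called and 15 positive. puc at 0.51 and Atf3 at 0.35 did not reach the threshold, and the list passed (adjusted p = 3.67e-07; adjusted p = 0.405 with an estimated correlation). Neurotransmitter receptors (26 genes, median 0.18, 24 positive) had 0 called genes, with Dop2R at 0.37 and GluRIA at 0.27 (adjusted p = 1.67e-05; adjusted p = 0.0815 with an estimated correlation). Ion channels (21 genes, median 0.12, 19 positive) also had 0, with Shaw at 0.33 and NaCP60E at 0.26. The list had adjusted p = 0.000669 (0.0815 with an estimated correlation). Against unexposed, the ion channel list mean ran from -0.26 to 0.04 in the air arrays. In the ethanol arrays it ran from -0.13 to 0.19, around the unexposed level. The ethanol-behavior list (33 genes, median 0.10) had 1 rising gene, Men. Other members, such as Tao at 0.22 and scb at 0.41, did not pass, while the list did (adjusted p = 0.002; adjusted p = 0.524 with an estimated correlation). The FOXO and fasting list (20 genes, median 0.14) had 0 called, with Pepck1 at 0.58 and bmm at 0.40 (adjusted p = 0.0101; adjusted p = 0.579 with an estimated correlation).

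Lower after ethanol were 8 lists, led by the odorant-binding proteins (24 genes, median -0.17, mean -0.64). In it 7 genes fell (Obp19a, Obp28a, Obp59a, Obp69a, Obp83b, Obp84a and lush; Obp28a by 1.28), 17 were not called, and 8 fell adjusted over the list alone (adjusted p = 8.39e-09; adjusted p = 0.405 with an estimated correlation). Of 13 antennal marker genes 12 were called lower (median -1.77), but 7 of them are these same list members; of the other 6 (a5, a10, Os-C, Orco, Antdh and Snmp1), Snmp1 was not called. The male reproductive tract list (18 genes, median -1.27, 0 called) included Acp53Ea at -2.08 and SP at -1.63 (adjusted p = 1.67e-05; adjusted p = 0.547 with an estimated correlation). The gut list (8 genes, median -1.82, 0 called) included Jon65Aiv at -2.11 (adjusted p = 0.002; adjusted p = 0.579 with an estimated correlation). Both lists stood above the unexposed arrays in the air arrays at 0 min (4.20 and 5.81 log2 as list means), 60 min (3.17 and 4.67) and 120 min (3.54 and 5.48). They did so in the ethanol array at 120 min too (1.96 and 4.86), and lay near 0 in the other arrays. Without the 0, 60 and 120 min pairs both lists turned upward (adjusted p = 0.409 and 0.561), and without the 0 min pair alone the gut list had 0.17.

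The other 5 lower lists shifted little per gene. Proteasome genes (26, median -0.06, 25 negative, 0 called, Rpt2 at -0.14) had adjusted p = 0.00782 (adjusted p = 0.84 with an estimated correlation). UDP-glycosyltransferases (15, median -0.11, 0 called) had 0.0121 (adjusted p = 0.579 with an estimated correlation; 0.0587 without 30 min; 0.0841 with no filter). Cytochrome P450 genes (50, median -0.12) held 1 rise, Cyp6d5, with 3 rising and 2 falling adjusted over the list alone. Cyp12e1 stood at -0.38 and Cyp12a4 at -0.45, and the list passed (adjusted p = 0.0234; adjusted p = 0.84 with an estimated correlation; 0.192 without 210 min). Oxidative phosphorylation genes (50, median -0.03, 49 negative, 0 called, ND-51 at -0.07) had 0.0307 (adjusted p = 0.84 with an estimated correlation). Hemocyte genes (15, median -0.08, 13 negative, 0 called, Glt at -0.27) had 0.0342 (adjusted p = 0.331 with an estimated correlation). Oxidative phosphorylation lost its call without 0 min (0.171), 30 min (0.0702), 60 min (0.118) or 120 min (0.328) and turned upward without the 0, 60 and 120 min pairs together (0.647). The hemocyte list lost it without 0 min (0.248), 30 min (0.0587), 60 min (0.0987), or the 0, 60 and 120 min pairs together (0.561).

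The remaining 19 lists did not pass. Glutathione S-transferases (29 genes) split: GstE7 and GstD2 rose, GstE4 fell, 26 were not called, and 4 rose and 3 fell adjusted over the list alone (median -0.05, mean 0.03, adjusted p = 0.573). Alcohol and acetate metabolism (12 genes, median -0.06, mean 0.04, test downward, adjusted p = 0.662) had 1 rise, Men. Immune effectors (16 genes, median 0.09, mean -0.01, adjusted p = 0.662) had 1 fall, Drsl5 by 0.37. Amino acid response genes and tRNA synthetases (27 genes, median 0.01, adjusted p = 0.662) had 2 rises, AsnS by 0.81 and aay by 0.61. The oxidative stress list (24 genes, median -0.02, adjusted p = 0.662) had 1, Prx6c. Drsl5, AsnS and aay were chosen after their values were seen. None of the other 14 had a called gene. They were clock (12 genes, median 0.06, adjusted p = 0.567), synaptic vesicle (18, 0.02, 0.0795), monoamine and neuropeptide (31, 0.03, 0.306), glycolysis (26, 0.00, 0.573) and lipid metabolism (28, 0.01, 0.497). Also among them were ribosomal proteins (33, -0.01, 0.686), endoplasmic reticulum stress (18, -0.01, 0.662), ecdysone (19, 0.03, 0.546) and JNK (17, 0.03, 0.0941). Cell and tissue lists were photoreceptor (21, 0.02, 0.313), glia (19, 0.01, 0.662), head fat body (9, 0.02, 0.725), muscle (22, -0.01, 0.662) and cuticle (18, -0.08, 0.0795).

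**Figure D2:**
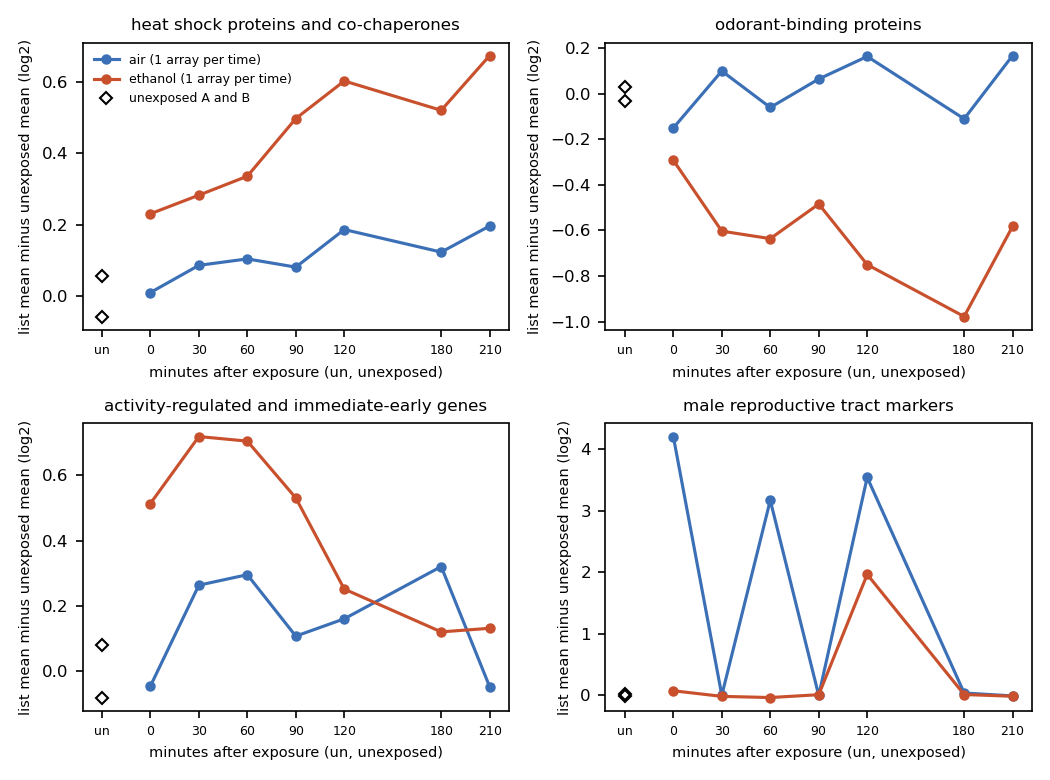
List mean minus the unexposed mean (log2, y axis) against minutes after exposure for heat shock, odorant-binding protein, activity-regulated and male reproductive tract genes; blue is air, orange is ethanol and diamonds are the unexposed arrays. The heat shock mean is higher and the odorant-binding protein mean lower after ethanol than after air, and the reproductive tract mean is raised in 4 arrays.

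The response to ethanol also changed over recovery. The difference in CG7227 fell by 0.76 log2 per hour (SE 0.09, adjusted p = 0.0361; n = 7 times), from 0.38 at 0 min to -1.90 at 210 min. Tdc1, a tyrosine decarboxylase gene (probe set 1635665_at; chromosome 2R, 6677001 to 6680391), fell by 0.62 per hour (SE 0.09, adjusted p = 0.0402), from 2.07 at 0 min to 0.21 at 210 min, and CG15673 by 0.64 per hour (SE 0.10, adjusted p = 0.0489), from 1.96 to 0.25. CG13086 fell by 0.66 per hour, Ass, which makes argininosuccinate, by 0.61, CG46491 by 0.55, Pcyt2 by 0.53 and CG14400 by 0.53 (all adjusted p = 0.0361), and Cyp4d1 by 0.57 and CG13116 by 0.54 (both 0.0402). The stress-induced DNase gene Sid rose by 0.67 per hour (SE 0.08, adjusted p = 0.0361) and CG16772 by 0.31 (SE 0.05, adjusted p = 0.0495). After ethanol Sid lay under the filter value of log2 4 at 0, 30 and 60 min (3.69, 3.69 and 3.59) and reached 6.33 and 5.86 at 180 and 210 min. In air it was above log2 4 only at 180 min (4.57), so its slope rests mainly on the late ethanol arrays. CG7227 ended under log2 4 after ethanol (3.81 and 3.73 at 180 and 210 min). The slope of sug, a sugar-responsive transcription factor gene, did not pass: -1.34 per hour (SE 0.25, adjusted p = 0.0707), from 2.45 at 0 min to -1.15 at 210 min.

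In all, 6 genes rose and 49 fell against time, with 1257 at unadjusted p < 0.05. The median slope of all genes was -0.05 per hour, and the counts were 4 rising and 14 falling with quantile scaling and 5 and 12 with median scaling. The count of 55 was 0 without any one of the 0, 30, 60, 90 or 120 min pairs, 1 without 180 min, and 0 with a body-tissue covariate. Without 210 min it was 69, with 21 of the 55 genes shared and 11 of 17 named calls kept. Comparing late with early times called 1 gene, sug (-4.23, adjusted p = 0.0137).

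Of 9 lists with a slope, cytochrome P450 genes (50, median -0.14 per hour) had the most called members: 6 fell (Cyp4d1, Cyp6a22 at -0.45, Cyp6t1 at -0.43, Cyp6g1 at -0.29, Cyp12a4 and Cyp4ac1, the last 2 named after their values were seen). In this list 44 were not called and 19 fell adjusted over the list alone (adjusted p = 2.35e-05; adjusted p = 0.348 with an estimated correlation). Ecdysone genes (19, median -0.15) had 1 fall, MsrA by 0.29, with 4 falling adjusted over the list alone and br at -0.23 (0.0196; adjusted p = 0.351 with an estimated correlation; 0.0742 without 210 min). Lipid genes (28, median -0.12) had 1, Lip4 by 0.32, with 1 rising and 4 falling adjusted over the list alone and Acox57D-p at -0.41 (0.0419; adjusted p = 0.594 with an estimated correlation; 0.0584 without 60 min and 0.945 without 210 min). Heat shock genes (11, median 0.01, 0 called) parted: 4 rose and 2 fell adjusted over the list alone, with Hsp27 at 0.36, Hsp26 at 0.34 and DnaJ-1 at -0.34 (0.00699; adjusted p = 0.348 with an estimated correlation; 0.0739 without the 0, 60 and 120 min pairs). Muscle genes (22, median 0.06, 21 positive, 0 called, Obsc at 0.20) had 8.64e-08 (adjusted p = 0.348 with an estimated correlation) and ion channels (21, median 0.02, 0 called) 0.0342 (adjusted p = 0.348 with an estimated correlation; 0.295 without 0 min and 0.211 without 180 min). The male reproductive (18, median 0.83) and gut (8, median 1.47) lists rose with 0 called genes (1.24e-09 and 5.97e-07; adjusted p = 0.348 with an estimated correlation for both). Without the 0, 60 and 120 min pairs both had 0.69. Oxidative phosphorylation genes (50, median below zero at -0.01, test upward, 0 called) had 0.00699 (adjusted p = 0.915 with an estimated correlation; 0.531 without 180 min). The 24 other lists had adjusted p between 0.0593 (hemocyte) and 0.927; Tdc1 in the monoamine list, Lip4 in the FOXO and fasting list and MsrA in the oxidative stress list were their named falls.

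By window, 3 genes passed early: sug (probe set 1624195_at; chromosome 2R, 12924567 to 12930644) rose by 2.60 log2 (SE 0.22, adjusted p = 0.0283), Tdc1 by 1.94 (SE 0.13, adjusted p = 0.0156) and CG15673 by 1.86 (SE 0.16, adjusted p = 0.0283), with 501 at unadjusted p < 0.05. Hr38 (0.73, adjusted p = 0.816), vri (0.67, 0.397) and AcCoAS (0.50, 0.792) did not pass. The 3 calls, all higher, became 13 without the 0 min pair (9 of them lower, 1 shared), 9 without 30 min (6 lower, 1 shared), 1 without 60 min or 90 min and 0 without 120 min.

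In the middle window limma called 0 genes, with 846 at unadjusted p < 0.05 and a smallest adjusted p of 0.0595; array weights called 70 and trend with robust variances 58. The smallest p-values were those of CG15673 (1.62), GstD2 (1.27), CG12290 (1.26), Spn27A (1.24), Dph1 (1.01) and Rnb (-1.34), all with adjusted p = 0.0595. Lower values were a10 (-1.53, adjusted p = 0.075), idc (-0.64, 0.0836), GstE4 (-2.37, 0.0899) and phu (-2.77, 0.105). Without the 0 min or the 30 min pair, 17 genes passed.

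In the late window 33 genes rose and 44 fell; gene lists were not tested by window. The storage protein gene Lsp2 (probe set 1641634_at; chromosome 3L, 12129393 to 12131869) rose by 2.61 log2 (SE 0.28, adjusted p = 0.0237), Gnmt, a glycine N-methyltransferase gene, by 2.18 (SE 0.27, adjusted p = 0.0273). Sid rose by 1.58 (SE 0.25, adjusted p = 0.0467), Nmdmc by 1.52 (SE 0.15, adjusted p = 0.019) and Hsp68 by 1.49 (SE 0.15, adjusted p = 0.019). Hsp26 rose by 1.19 (adjusted p = 0.0135) and sug, high early, now fell by 1.63 (adjusted p = 0.0237). The largest falls were those of Obp59a (-3.20, adjusted p = 0.0273), a5 (-2.97, 0.019), Obp84a (-2.83, 0.0425), Os-C (-2.59, 0.0273) and Jhedup (-2.46, 0.0329). After ethanol at 180 min Obp59a and Obp84a lay under the filter value of log2 4 (2.54 and 2.67), so the size of their falls is less certain. Of 77 late genes (974 at unadjusted p < 0.05), 31 were also called over all times, in the same direction. The count was 0 without the 180 min or the 210 min pair, 23 without 60 or 90 min, 39 without 120 min and 46 without 0 or 30 min.

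**Figure D3:**
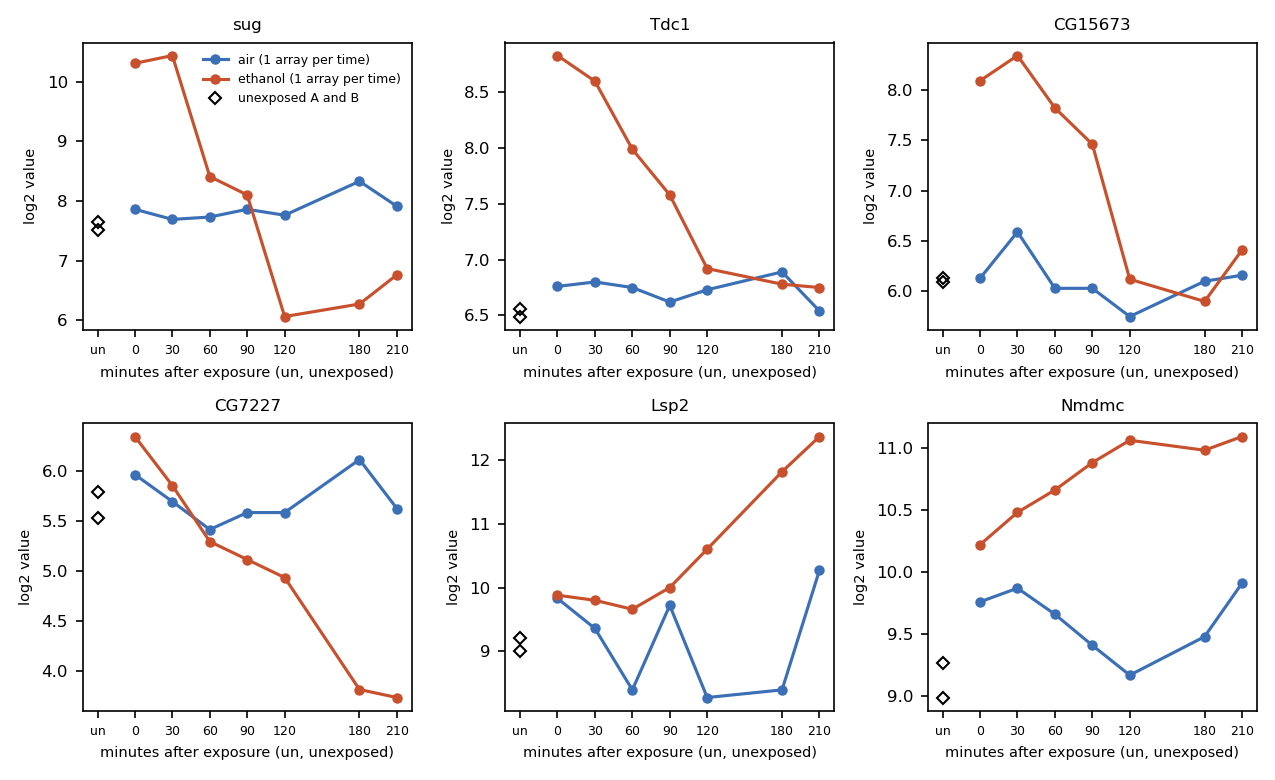
Expression (log2, y axis) of sug, Tdc1, CG15673, CG7227, Lsp2 and Nmdmc in each array against minutes after exposure; blue is air, orange is ethanol and diamonds are the unexposed arrays. sug and Tdc1 differ most at 0 and 30 min, Lsp2 at 180 min and Nmdmc at 120 min.

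Handling with air alone was compared with no exposure (7 against 2 arrays), and limma called 0 genes, with 520 at unadjusted p < 0.05; array weights called 21 and trend with robust variances 2. The smallest p-values above unexposed were those of CG34134 (1.84, SE 0.33, adjusted p = 0.0849), AhcyL1 (1.58, SE 0.26, adjusted p = 0.0804), CG15282 (0.99, 0.142), CG7300 (0.64, 0.0849) and CG10257 (0.43, 0.152). Below unexposed stood Amun (-0.78, SE 0.12, adjusted p = 0.0626), kirre (-0.62, 0.103), Rbp (-1.02, 0.152), Dlic (-0.92, 0.233) and Appl (-0.53, 0.233). The count became 10 without the air array at 210 min, 1 without air 60 min or unexposed A, and 7 with only air and unexposed arrays in the model.

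Of 33 lists, 8 differed between air and unexposed, none with a called gene. Immune effectors (16 genes, median 0.32) stood higher, 4 of them adjusted over the list alone, with pirk at 1.25 and Rel at 0.60 (adjusted p = 0.000877; adjusted p = 0.558 with an estimated correlation). UDP-glycosyltransferases (15, median 0.22, 2 higher adjusted over the list alone, Ugt36F1 at 0.65) had 0.000703 (adjusted p = 0.558 with an estimated correlation). Proteasome genes (26, median 0.10) had 0.00346 (adjusted p = 0.912 with an estimated correlation). Lower were ion channels (21, median -0.07, 3 lower adjusted over the list alone, SK at -0.65; 0.000703; adjusted p = 0.558 with an estimated correlation) and neurotransmitter receptors (26, median -0.03, Rdl at -0.71; 0.00768; adjusted p = 0.71 with an estimated correlation). The clock list passed on the lower side (12 genes, median -0.07, 6 above and 6 below unexposed, 0 called, Pdp1 at -0.65, tim at -0.53; 0.0455; adjusted p = 0.558 with an estimated correlation; 0.0624, 0.0609, 0.142 and 0.175 without air 0, 120 or 180 min or unexposed B). The male reproductive (18, median 1.42, 0.0109) and gut (8, median 2.64, 0.0455) lists were higher (adjusted p = 0.912 with an estimated correlation for both). Without the 4 arrays in which they are raised both turned downward (0.281 and 0.444). With 1 array left out they had 0.129 and 0.21 (air 0 min), 0.0512 and 0.199 (air 60 min), 0.0783 and 0.176 (air 120 min) and 0.399 and 0.496 (unexposed A). The 25 others had adjusted p between 0.062 and 0.963. Ion channels, neurotransmitter receptors, proteasome genes and UDP-glycosyltransferases also passed for ethanol against air, in the opposite direction. Both comparisons use the same air arrays. For these lists, a shift in the air arrays alone cannot be told apart from separate effects of handling and of ethanol.

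Over the 7 air arrays alone, limma called 0 genes for a slope with time, with 822 at unadjusted p < 0.05; array weights and trend with robust variances also called 0, and 1 passed without the air array at 30 min. The smallest p-values were those of the antibacterial peptide gene DptB (0.66 per hour, SE 0.10), CG13606 (0.32), BomBc3 (0.28), Arpc1 (0.26) and CG14696 (0.21), all with adjusted p = 0.164. On the falling side were CG10513 (-0.20, 0.207), CG34134 (-0.30, 0.24), Jhe (-0.44, 0.276), Jhbp15 (-0.22, 0.302) and Fmo-2 (-0.17, 0.334). The clock genes per (0.26 per hour, adjusted p = 0.3) and tim (0.25, 0.335) climbed in air without passing. The male reproductive (18 genes, median -0.76, adjusted p = 1.1e-11) and gut (8 genes, median -1.27, 5.65e-07) lists, raised in the air arrays at 0, 60 and 120 min, fell (adjusted p = 0.999 with an estimated correlation for both; 0.154 and 0.254 without those 3 arrays). The FOXO and fasting list (20 genes, median 0.02, mean -0.01, test downward) had 0.0491 (adjusted p = 0.999 with an estimated correlation; 0.258, 0.181, 0.0731, 0.11 and 0.152 without 0, 30, 60, 120 or 180 min). The other 30 lists had 0.132 to 0.997.

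With 1 slope shared by the air and ethanol arrays, 346 genes passed (290 rising, 56 falling), but this fit counts the 2 arrays of a time as independent. With the mean of both arrays at each time (7 values, an alternative chosen after the result was seen), 33 passed (22 rising, 11 falling; 28 shared; 1243 at unadjusted p < 0.05). BomBc3 rose by 0.44 per hour (adjusted p = 0.00443 from the time means), CG4269 by 0.52 (0.0159), CG8306 by 0.23 (0.0117) and GstD2 by 0.48 (0.0329). The clock genes tim (0.24 per hour; 0.25 in air and 0.23 after ethanol) and per (0.25; 0.26 and 0.24) passed with the arrays counted singly (adjusted p = 0.00662 and 0.0114) and not from the time means (0.08 and 0.1). The same held for CG34134 (-0.31, 0.00729 against 0.0888) and Jhe, a juvenile hormone esterase gene (-0.42, 0.0117 against 0.0992). With the arrays counted singly 8 lists passed: upward muscle (adjusted p = 5.35e-05), ion channels (0.00413) and oxidative phosphorylation (0.0422), and downward FOXO and fasting (0.00413), male reproductive tract (0.00413), cytochrome P450 (0.00496), activity-regulated (0.019) and lipid genes (0.019). None passed with an estimated correlation (0.53 to 0.817). The other 25 did not pass, clock genes (2 of 12 rising, adjusted p = 0.89) and immune effectors (2 of 16 rising, 0.0866) among them. BomBc3, CG4269, CG8306, GstD2 and Jhe were chosen after the values were seen. tim stood at 11.83 and 11.65 in the unexposed arrays, near its level in the late air arrays (11.56 to 11.68), and was lower at 0 min (10.91 after air, 11.02 after ethanol).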

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

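The tests of body tissue, handling and ethanol exposure as sources of the body-tissue transcripts were chosen after the result was seen. So were those of dilution and of chance antennal content, that of body-tissue RNA behind the ethanol calls and the reordering of times. The tests on Orco, Snmp1 and Antdh, on odorant-binding protein genes outside the antenna and on swaps and splits of the arrays were written before they were run. The antennal tests among them address a fall that is itself a result of these data. They were not among the comparisons chosen before the data were examined.

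Among the 7 arrays of each exposure, 150 groups of values were searched for a single array far from the other 6, and 10 were found, where chance alone gives about 1 in 20. Both largest gaps were in the ethanol array at 120 min: its male reproductive tract list mean was 1.962 log2 above unexposed (next highest ethanol array 0.071) and its gut list mean 4.859 (next 0.033). Single genes were Sid in the air array at 180 min (4.57 against 3.71 in the next), Arc2 in the air array at 0 min (5.58, next lowest 5.93) and CG32512 in the ethanol array at 0 min (6.69, next lowest 8.05). In the air arrays the monoamine and neuropeptide list stood apart at 180 min (0.254, next 0.075), the JNK list at 180 min (0.299, next 0.143), the alcohol metabolism list at 210 min (0.229, next 0.08) and the lipid list at 210 min (0.12, next 0.025). In the ethanol arrays the monoamine and neuropeptide list stood apart at 0 min (0.277, next 0.097). Over all genes, the median ethanol minus air difference was 0.15 log2 at 0 min and -0.17 at 180 min. For the lists that stood apart at these times, a shift of the list cannot be told apart from a shift over all genes of the array.

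Transcripts of the male reproductive tract and gut were high in 4 arrays: air at 0, 60 and 120 min and ethanol at 120 min. The smallest of 12 medians (accessory gland, testis and gut genes in the 4 arrays) was 1.612 log2 above unexposed, while in the other 12 arrays the largest absolute median was 0.041. A response to handling or recovery time is argued against by the air arrays at 30 and 90 min, whose higher marker mean was 0.0055. The ethanol exposure is argued against by the times: air exceeded ethanol by over 0.5 log2 units at 3 of 7. Body tissue carried over with the heads of those pools may be the source, and whether it entered at dissection or at extraction stays open.

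Antennal transcripts were lower in the ethanol arrays, with median differences between -1.44 and -2.49 log2 from 30 to 210 min. At 0 min the median difference was -0.22 (marker mean minus unexposed -0.87 in the air array and -1.20 in the ethanol array). A fall of odorant-binding protein genes wherever they are expressed is argued against by the 13 that act mainly outside the antenna (median -0.149, 10 of 13 below 0, 0 called lower). Dilution of the ethanol arrays by body tissue is argued against by the median fall of -2.134 over 30, 60, 90, 180 and 210 min, whose ethanol arrays are not raised. The 0 min pair (-0.22), whose ethanol array is not raised either, was left out of that median. Chance antennal content is argued against by a range of 1.252 over the 9 arrays without ethanol, smaller than the mean fall of 1.69. A lower share of antennal tissue in the ethanol arrays cannot be told apart from regulation inside the antenna: Orco, Snmp1 and Antdh had a median of -0.871, between the bounds set for and against it. A response of antennal cells to ethanol stays among the open explanations, as untested.

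The ethanol minus air difference changed with recovery time in 55 genes, tested as a slope per hour. Falling were CG7227 (-0.764), CG13086 (-0.657), CG15673 (-0.635), Tdc1 (-0.619), Ass (-0.608), Cyp4d1 (-0.571), CG46491 (-0.548), CG13116 (-0.536), Pcyt2 (-0.531), CG14400 (-0.527), Cyp6a22 (-0.452), Cyp6t1 (-0.428), Lip4 (-0.321), Cyp6g1 (-0.286) and MsrA (-0.286); rising were CG16772 (0.307) and Sid (0.672). As lists, the median slopes were -0.139 for cytochrome P450, -0.145 for ecdysone, -0.116 for lipid, -0.005 for oxidative phosphorylation, 0.01 for heat shock, 0.019 for ion channel, 0.055 for muscle, 0.83 for male reproductive tract and 1.47 for gut genes. Reordering the times of the 7 matched differences gave as many genes in 1 of 100 orders, the real one (55, highest other 47). That share argues against chance order for the count, though another order came near it. The reordering does not test the body-tissue transcripts, which are uneven over time. Swapping exposure within times (1 of 64 ways, highest other 0) tests whether ethanol has an effect and decides nothing about time. The count was 0 without any one of the 0, 30, 60, 90 or 120 min pairs, with array weights and with the body-tissue covariate.

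The count of 56 genes changed by ethanol was reached in 1 of 64 ways of swapping exposure within times, the real one (highest other 0). That share argues against chance for the count as a whole, not for single genes. The count was also reached in 1 of 100 random splits of the 14 arrays, the real one (highest other 15). Most of those splits part the arrays at fewer than 7 times. In a fit matched by time their counts are low by construction, so they decide nothing. For the late window the 16 swaps are too few for a share under 0.05 (real 77, highest other 0). Body-tissue RNA in 4 arrays is argued against as the source of 23 of the 56 calls, which a fit of the 30, 90, 180 and 210 min pairs alone, free of those arrays, also called in the same direction. A further 13 stayed called with the body-tissue score as a covariate in a fit of all 7 pairs. The score is the mean log2 value of reproductive tract and gut markers, whose mix differed between arrays. Their list means were 1.96 and 4.86 in the ethanol array at 120 min, and 4.20 and 5.81 in the air array at 0 min. For these 13 the fit argues only against body-tissue RNA that follows the score, and RNA of another mix stays possible. For the last 20, called in neither fit, body-tissue RNA cannot be told apart from a loss of precision. Of these, 0 changed sign in either fit. With the covariate their median absolute difference went from 0.55 to 0.51 log2 and their median SE from 0.08 to 0.11.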

How the results depend on the processing

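Leaving out the 0, 60 and 120 min pairs (or the raised arrays), the body-tissue covariate and the slope of time means were chosen after the result was seen. No single gene past the threshold reversed, and each alternative gave a value. Of the single named results, 4927 stayed on their side of the threshold, 442 lost their call and 149 gained one. The 4927 include results not called in the main fit, which had no call to lose. The 442 are therefore a larger share of the called results than of all of them. Except where a cause is given, the cause was not tested.

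For ethanol against air, 56 genes became 0 with no filter (17104 genes tested), 150 with array weights, 111 at adjusted p < 0.10 (a wider threshold) and 24 without the 0, 60 and 120 min pairs (fewer arrays; 23 shared). Leaving out 1 pair gave 8 (without 60 min) to 104 (without 0 min). Counts within 1.5 times were 66 with the filter at log2 6, 74 with quantile and 79 with median scaling, 53 with all probe sets, 77 with trend and robust variances, 44 with a 1.5-fold minimum, 46 with the body-tissue covariate (35 shared) and 45 without matching by time (37 shared). Without matching by time, 18 of 25 named calls were kept with time left out and 24 with minutes as a linear term.

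For the change with time, 55 genes became 9 with no filter, 18 with quantile (4 rising, 14 falling) and 17 with median scaling (5 and 12), 151 with trend and robust variances, 0 with array weights, 146 at adjusted p < 0.10, 0 without the 0, 60 and 120 min pairs, 1 when late and early times were compared, 19 without matching by time and 0 with the body-tissue covariate. Leaving out 1 pair gave 0 to 69.

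The 3 early genes became 0 with no filter, 7 with the filter at log2 6, 6 with median scaling, 10 with trend and robust variances, 1 with array weights, 7 at adjusted p < 0.10, 16 without the 0, 60 and 120 min pairs and 0 with the covariate; leaving out 1 pair gave 0 to 13. The 0 middle genes became 15 with the filter at log2 6, 5 with quantile and 7 with median scaling, 58 with trend and robust variances, 70 with array weights, 19 at adjusted p < 0.10 and 8 without the 0, 60 and 120 min pairs; leaving out 1 pair gave 0 to 17. The 77 late genes became 3 with no filter, 187 with trend and robust variances and 150 at adjusted p < 0.10; leaving out 1 pair gave 0 to 46. They were 77 again (46 shared) without the 0, 60 and 120 min pairs and 87 with the covariate.

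For air against unexposed, 0 genes became 10 with no filter, 1 with the filter at log2 6, 2 with trend and robust variances, 21 with array weights, 4 at adjusted p < 0.10 and 7 with only air and unexposed arrays; leaving out 1 array gave 0 to 10. For the slope in air, 0 became 1 with no filter, 346 with a slope shared by both exposures (air and ethanol arrays of a time counted as independent) and 33 with the mean of both arrays at each time; leaving out 1 array gave 0 to 1.

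With an estimated correlation 0 lists passed in each comparison, against 14 for ethanol, 9 for the change with time, 8 for air against unexposed and 3 for the slope in air. With fry it was 5, 5, 0 and 0. For ethanol against air, no list passed the exact sign-flip test after adjustment (smallest adjusted p = 0.172). Leaving out 1 array moved the 8 lists to between 5 and 9 and the 3 lists to between 2 and 9; the 3 became 17 with no filter and 0 with the covariate.

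Some lists turned direction. The male reproductive tract and gut lists, lower for ethanol against air, stood higher without the 0, 60 and 120 min pairs (0.409 and 0.561) and with the covariate (0.64 and 0.0888). For air against unexposed they turned from higher to lower without the 4 raised arrays (0.281 and 0.444) and with the covariate (0.307 and 0.0425, the gut list past the threshold in the opposite direction). Both alternatives remove the arrays or the signal that raised them. Oxidative phosphorylation turned upward for ethanol without the 0, 60 and 120 min pairs (0.647); under fry its slope turned (0.966), as did the slope of the FOXO and fasting list in air (0.878).

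The evenness of array medians and of the share above log2 4 is set by quantile normalization, so what signal over background limits was not measured.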

Other observations

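The test of handling and the late-window genes named here were chosen after the result was seen.

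Single genes called in the late window beside those of the rule include Shmt, which rose by 0.75 log2 (SE 0.11, adjusted p = 0.035), and Pepck2, which rose by 0.96 (SE 0.13, adjusted p = 0.035). Hsp27 rose by 1.07 (SE 0.15, adjusted p = 0.0354), BomBc3 by 0.88 (SE 0.14, adjusted p = 0.0463) and FoxP by 0.65 (SE 0.08, adjusted p = 0.0273). Agxt fell by 1.03 (SE 0.09, adjusted p = 0.0157) and BomS6 was lower (-0.56, SE 0.09, adjusted p = 0.0499). They are single genes, and no list was tested in this window.

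As values without a test, the odorant-binding protein list mean in the ethanol arrays was -0.29 against unexposed at 0 min and -0.98 at 180 min. The heat shock list mean was 0.23 at 0 min and 0.67 at 210 min. The activity-regulated list mean was 0.51 at 0 min, 0.72 at 30 min and 0.12 at 180 min after ethanol, and -0.05, 0.26 and 0.32 after air; its change with time did not pass (adjusted p = 0.0622).

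Whether genes higher after ethanol also respond to the handling that both exposures share was tested against unexposed flies. Over the 4 air arrays without body tissue, the 34 genes higher after ethanol stood a median of 0.198 log2 above unexposed (27 of 34 above), higher than all of 10000 random gene sets (median 0.068). The 22 genes lower after ethanol also stood above unexposed, by a median of 0.132 (3 of 22 below; above 96.4% of random sets, median 0.075). For these genes the test decides nothing, since being called lower than air selects genes that are high in the same air arrays. Both groups stood high against unexposed, and a shift unrelated to the direction after ethanol may account for part of the 0.198. The unexposed side rests on 2 arrays, and random sets of genes do not measure the spread between arrays. The air arrays also come from different recovery times, while the unexposed arrays have none. For the 34 genes, handling therefore cannot be told apart from recovery time or from differences between single arrays.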
